A study of Homo sapiens with 24 samples.

How the data were processed

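The series holds 24 RNA-seq libraries of MOLT4, a human T-cell acute lymphoblastic leukaemia line, treated with SK-3-91, which the labels call a pan-kinase degrader, or with its solvent DMSO. Cells were harvested at 1, 4 and 8 h, with 4 replicates in each of the 6 groups. Per the labels' protocols, total RNA was extracted and sequenced on the BGISEQ-500 as single-end reads of 50 bases; the dose was not given in the sources used here. A degrader of this kind carries a kinase-binding part and a part that recruits a ubiquitin ligase.

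The authors' deposited count table gives whole-number read counts per Entrez gene and library, not normalized. Per the submitters' processing notes, edgeR was used and the genome build was hg19; the aligner, counting tool, strand setting and annotation were not given in the sources used here. The table holds 9822 genes, of which 9818 have a symbol. It had been restricted before deposit: the lowest mean count of a gene was 32.04, and 4 of 1050 single-exon protein-coding genes of GENCODE release 29 were in it, against 9350 of 18886 multi-exon genes (49.5%). Of the symbols, 9757 (99.4%) matched that annotation, which was used for transcript length, GC content, shared sequence and overlap with exons on the opposite strand. Because its build differs from hg19, no coordinates are given. JUN, CDKN1A, HEXIM1 and PTK2 were not analysed here. A column of gene width deposited with the counts entered no test.

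A second table named by the authors for RPKM values turned out to hold deposited log2 values: 2 to the power of each value was a straight line in the same library's count for all genes, with a largest relative gap of 3.9e-07%, whatever the gene's width. Those values therefore carry no gene length, and the planned fits on log2(RPKM + 0.1) and log2(RPKM + 1) were not run. limma-trend on the deposited log2 values as they stand took their place, an alternative chosen after seeing the data.

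Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM factors, filterByExpr (which removed 0 genes), group means over all 24 libraries with 1 shared estimate of the spread, quasi-likelihood F tests, and Benjamini-Hochberg adjustment per comparison at 0.05. The common biological coefficient of variation was 0.0422. SK-3-91 was compared with DMSO at each time. Differences between times in that response, and changes over time in DMSO alone, were tested as contrasts of the same model. Standard errors are those implied by the F statistic, and CPM values are scaled by TMM. TMM assumes that most genes keep their share, so fold changes are relative to the other genes and not per cell. Totals of counted reads were compared with exact two-sided permutation tests. Depth ranged from 6.863 megareads counted in the shallowest library to 14.626 megareads in the deepest. The median standard error of a log2 fold change was 0.058 at 1 h, 0.062 at 4 h and 0.067 at 8 h. Counting intervals are 95% exact binomial (Clopper-Pearson) intervals and cover counting error only.

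Before the data were examined, 32 gene lists, 20 fixed genes, the gene and list tests of the report and all but 1 of the alternatives were chosen. Lists with at least 5 measured members (25 of 32) were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with an inter-gene correlation preset to 0.01, adjusted over the 75 list and time pairs; 18 pairs passed, and 3 did with an estimated correlation. Member counts adjusted over the list alone equalled those adjusted over all genes in 63 of the 75 pairs and differed by at most 4 members. The lists covered immediate-early, ERK, FOXO, MYC nucleolar, Notch, JAK-STAT, NF-kB, T-cell activation, T-lineage, T-leukaemia transcription factor, p53, ATF4, unfolded protein, heat-shock, sterol, glycolysis and hypoxia, interferon, G1/S, G2/M, CDK12-dependent DNA repair, BCL-2, CRBN ligase, histone, ribosomal protein, mitochondrial, CDK and protein kinase genes, and markers of B, myeloid, erythroid, epithelial, and fibroblast or endothelial cells.

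Genes were named by a rule. At each time it took the 8 largest increases and the 8 largest decreases with an adjusted p under 0.05, a mean CPM of at least 5 in the higher group and all 4 treated libraries on one side of all 4 DMSO libraries. It passed over ZNF443, which shares sequence with a near-identical copy, and 1 gene without a symbol. It also took up to 4 called members per list with a mean CPM of at least 2, and the fixed genes whatever their result. Of the genes it took, 2 are not reported here, but they stay in all counts and tests. Genes sharing 32-base words with other genes, or exons with a gene on the opposite strand, are given as uncertain where either share is 20% or more, a limit chosen after the shares were seen, since the strand setting is not known. Shares from 10% to under 20% were found for MZF1, ZC3H10, C17orf97, PHLDA1, CCNF, AURKA, CDK7, HSPB1, RPLP1, RPLP2, IGLL1, ULBP1 and MSMO1, which carry the same doubt to a lesser degree.

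Alternatives were RLE, upper-quartile and no scaling factors, 2 filters, DESeq2 1.42.0, a robust fit, only the groups compared, a minimum fold of 1.5, the replicate number as a block, and leaving out each library. The pipeline was tested on simulated counts with 50 genes changed at each fold. At a fold of 1.2 it recovered 34 of 50 in the 1 h and the 4 h comparison (9818 genes) and 37 of 50 in the 8 h comparison (9819 genes). At a fold of 2 it recovered 50 of 50 in each. Of 9622 unchanged genes, 7, 10 and 10 were called. The simulated changes were few and went up and down in equal numbers. They thus do not test the TMM assumption that most genes keep their share, while edgeR called most genes in the real data. Python 3.11 drew the figures. The lowest chi-square per degree of freedom between replicates was 1.63, above what counting error alone gives. No pair thus looked like the same library sequenced again, but separate libraries of the same RNA are not excluded.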

Results

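Gene expression was measured in MOLT4 leukaemia cells exposed to the pan-kinase degrader SK-3-91 or to DMSO for 1, 4 or 8 h, with 4 libraries per group. Nothing in the labels says that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. Counted reads, in megareads (M), averaged 14.1 ± 0.126 M in DMSO and 13.6 ± 0.032 M in SK-3-91 at 1 h (SD, n = 4). At 4 h they averaged 14.4 ± 0.117 and 10.8 ± 0.097 M, and at 8 h 14.2 ± 0.464 and 8.3 ± 0.982 M. Treated totals were thus 96.2%, 74.7% and 58.3% of the DMSO totals, each with an exact permutation p = 0.0286 (two-sided, n = 4 against 4), the smallest p that this design allows. The first principal component of log2 CPM held 81.6% of the variance and the second 9%.

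**Figure D1:**
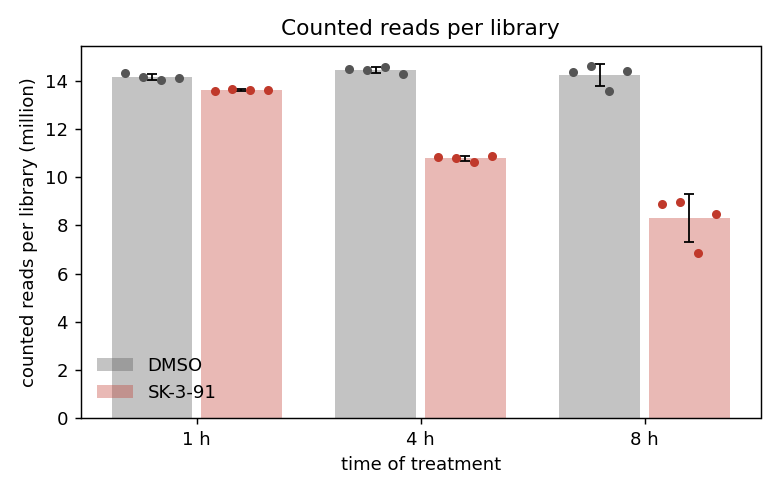
Counted reads per library, in megareads (M), by treatment and time; points are libraries, bars their mean and error bars the SD (n = 4). DMSO libraries lie between 13.567 and 14.626 M at all times, and SK-3-91 libraries at 8 h between 6.863 and 8.963 M.

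**Figure D2:**
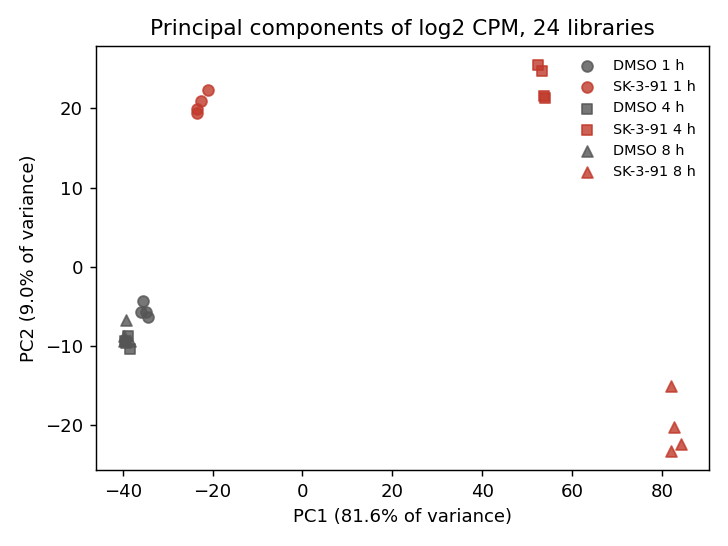
Principal components 1 and 2 of log2 CPM, 1 point per library, with the percentage of variance on each axis (81.6% and 9%).

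The 1 h comparison asked which transcripts respond first to the degrader. ID3, an inhibitor of DNA binding by helix-loop-helix factors, fell from 41.3 to 6.12 CPM (log2 fold change -2.75 ± 0.09, SE, n = 4 per group; edgeR adjusted p = 5.4e-25). CISH, a feedback inhibitor of cytokine signalling, fell by 2.54 ± 0.14 on the log2 scale, and PARS2, a mitochondrial prolyl-tRNA synthetase, by 2.30 ± 0.13. The other largest decreases were in the zinc-finger genes ZNF627 (-2.38), ZC3H10 (-2.21), ZNF823 (-2.20), ZNF2 (-2.12) and ZNF526 (-2.12). Increases among genes reaching a mean of 5 CPM were smaller: MIR210HG, a microRNA host transcript, rose by 1.15 ± 0.16, MASP2 by 0.94 ± 0.15, the arrestin-domain gene ARRDC3 by 0.70 ± 0.07 and GFRA4 by 0.67 ± 0.14. MZF1 (0.65), GSDMB (0.62), LINC00641 (0.62) and CCDC18-AS1 (0.61) also rose. Of 9822 genes, edgeR called 2448 higher and 2889 lower (54.3%), of which 5 were at least 2-fold higher and 319 at least 2-fold lower. Besides MIR210HG, the 5 were SLC26A5 (3.04 ± 0.43, from a mean of 2.5 to 20.5 counts), PRSS12 (2.12 ± 0.30), NNAT (1.42 ± 0.21) and LINC02603 (1.88 ± 0.25), which is uncertain because 85.7% of its exon bases lie in exons on the opposite strand; these were named after their values were seen. Which direction held more calls depended on the scaling: RLE factors gave 3249 higher and 2573 lower, DESeq2 3214 and 2536, and no scaling factors 1988 and 3079. Tested against a minimum fold of 1.5, 5 genes were higher and 573 lower.

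Signal-dependent genes fell together at 1 h. Some lists of the report share members, so their results are not independent. EGR1 is in the immediate-early and ERK lists, BTG2 in the immediate-early and p53 lists, and BCL6 in the FOXO and JAK-STAT lists. MYC and NOTCH1 are in the Notch and T-leukaemia circuit lists. The counts cover only members measured: 14 of 32 immediate-early genes, 12 of 26 ERK genes and 10 of 16 JAK-STAT targets. Of 14 measured immediate-early genes, 11 fell and 0 rose, with a median of -0.94 (camera adjusted p = 5.3e-07, and adjusted p = 0.019 with an estimated correlation); DUSP1 changed by -2.08, BTG2 by -1.76 and KLF10 by -1.57. Of 12 ERK feedback and output genes, 9 fell and 1 rose (median -0.66, camera adjusted p = 9e-04, adjusted p = 0.023 with an estimated correlation), among them the phosphatases DUSP2 (-1.72) and DUSP5 (-1.20) and the ERK inhibitor SPRY1 (-0.80). Of 10 JAK-STAT cytokine targets, 8 fell and 1 rose (median -0.50, camera adjusted p = 0.004, adjusted p = 0.046 with an estimated correlation), including the kinase gene PIM1 (-1.95) and SOCS1 (-1.31). These 3 lists were the only ones at any time to pass with an estimated correlation.

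FOXO-induced genes also fell at 1 h, 15 of 21 with 0 higher (median -0.42, camera adjusted p = 1e-04, adjusted p = 0.068 with an estimated correlation). They included the CDK inhibitor gene CDKN1B (-1.94 ± 0.07), BCL6 (-1.50) and the ubiquitin ligase gene FBXO32 (-1.42). Of 14 NF-kB targets, 9 fell and 1 rose (median -0.31, camera adjusted p = 0.011, adjusted p = 0.21 with an estimated correlation), among them BIRC3 (-1.25) and NFKBIA (-1.09), which encodes an NF-kB inhibitor, and IRF1 (-1.64), which shares 22% of its exon bases with the opposite strand and is uncertain. Of 24 p53 targets, 12 fell (13 adjusted over the list alone) and 4 rose (median -0.23, camera adjusted p = 0.012, adjusted p = 0.18 with an estimated correlation), with the phosphatase gene PPM1D at -1.56 and PLK3 at -1.37.

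Other lists were shifted upward at 1 h by small amounts. Ribosomal protein genes rose in 58 of 69 (62 adjusted over the list alone) and fell in 1, with a median of 0.25 (camera adjusted p = 8.8e-11, adjusted p = 0.36 with an estimated correlation); RPS15A rose by 0.39 and RPLP2 by 0.35. RPS15A and the member that fell, RPS3A (-0.53), share 25.3% and 76.9% of their sequence words with other genes and are uncertain. Glycolysis and hypoxia genes rose in 18 of 30 and fell in 5 (median 0.23, camera adjusted p = 0.012, adjusted p = 0.48 with an estimated correlation), but the largest called changes were decreases, in the repressor gene BHLHE40 (-1.31), the prolyl hydroxylase gene EGLN3 (-0.63) and the glucose transporter gene SLC2A1 (-0.57). Heat-shock genes rose in 13 of 18 and fell in 3 (median 0.18, camera adjusted p = 0.018, adjusted p = 0.33 with an estimated correlation); the co-chaperone genes BAG3 (-0.81) and DNAJB1 (-0.68) fell and HSPB1 rose by 0.34.

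The 4 h comparison asked how the response developed. EOMES, a T-box transcription factor, fell from 11.8 to 0.39 CPM (log2 fold change -4.88 ± 0.22, SE, n = 4 per group; edgeR adjusted p = 1.4e-22), and PDCD1, an inhibitory receptor of T cells, from 31.1 to 1.5 CPM (-4.36 ± 0.14). ADM, which encodes the peptide adrenomedullin, changed by -4.14, and C17orf97 (-4.57), ZNF200 (-4.53), PARS2 (-4.34), ZC3H10 (-4.28) and ZSWIM3 (-4.18) fell to a like degree. SLC26A5, the gene of the motor protein prestin, rose from 5 summed counts to 471, a ratio of 155 (95% counting interval 66 to 480). PPP2R3A, a phosphatase regulatory subunit gene, rose by 3.98 ± 0.14, PKD1L3 by 3.85, LSMEM1 by 3.73, PRSS12 by 3.64, LINC00926 by 3.53 and NNAT by 3.50. LINC02603, uncertain as at 1 h, rose by 3.70. edgeR called 4121 genes higher and 4511 lower (87.9% of 9822), 904 and 1786 of them at least 2-fold. Without scaling factors the split was 2871 higher and 5752 lower, because the median of all genes moved by -0.30, and 250 genes turned direction. Tested against a minimum fold of 1.5, 1938 were higher and 2525 lower.

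Cell-cycle genes fell at 4 h. Of 49 G2/M genes, 36 fell and 10 rose (median -0.66, camera adjusted p = 0.0012, adjusted p = 0.22 with an estimated correlation), among them the cyclin gene CCNF (-2.02), the centromere histone gene CENPA (-1.76) and AURKA (-1.75). Of 45 G1/S genes, 31 fell and 13 rose (median -0.48, camera adjusted p = 0.016, adjusted p = 0.29 with an estimated correlation); the exonuclease gene EXO1 changed by -3.22, the cyclin E gene CCNE1 by -2.13 and CHAF1A by -1.79. Notch targets fell in 11 of 13 and rose in 2 (median -0.88, camera adjusted p = 0.018, adjusted p = 0.18 with an estimated correlation), with DTX1 at -1.96, GIMAP7 at -1.35 and NOTCH1 at -1.11. The T-leukaemia transcription factor circuit fell in 12 of 15 and rose in 2 (median -0.64, camera adjusted p = 0.038, adjusted p = 0.3 with an estimated correlation), with MYB at -2.18 ± 0.04 and ERG at -1.42. All 69 measured ribosomal protein genes rose (median 1.2, camera adjusted p = 2.1e-16, adjusted p = 0.29 with an estimated correlation), RPS28 and RPLP2 by 1.52 and 1.51, while the treated total of counted reads was 74.7% of DMSO. RPS28 shares 21.4% of its exon bases with the opposite strand and is uncertain. Their median without scaling factors was 0.90.

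The 8 h comparison asked what the latest measured state was. TNFSF13B, the gene of the B-cell survival cytokine BAFF, rose from 0.243 to 38.3 CPM (log2 fold change 7.25 ± 0.20, SE, n = 4 per group; edgeR adjusted p = 1.3e-30), and AMH, the gene of anti-Müllerian hormone, from 3.84 to 115 CPM (4.90 ± 0.12). SLC26A5 rose from 8 summed counts to 788, a ratio of 228 (95% counting interval 115 to 529). PKD1L3 rose by 5.74, LINC00926 by 5.22, PPP2R3A by 5.20, the small GTPase gene RASL11A by 5.04 and PHLDA1 by 4.89. ADM fell from 37.8 to 0.89 CPM (-5.38 ± 0.21), ZNF672 from 89 to 2.94 CPM (-4.94 ± 0.10), PDCD1 by 4.85 and C17orf97 by 4.74 on the log2 scale. Ratios of summed counts were 46.1-fold lower for the phosphatase gene DUSP5 (95% counting interval 15.6 to 225), 36.3-fold for EOMES (18.3 to 84.4), 34.8-fold for ULBP1 (18.8 to 72.8) and 29.4-fold for RAB20 (13.4 to 80.6). edgeR called 4060 genes higher and 4723 lower (89.4% of 9822), 1652 and 2306 of them at least 2-fold. Without scaling factors the split was 2778 higher and 6145 lower, with a median shift of -0.43 and 481 genes turned in direction; upper-quartile factors moved the median by -0.17. Tested against a minimum fold of 1.5, 2496 were higher and 3052 lower.

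G1/S genes fell at 8 h as a list, 36 of 45 lower and 9 higher (median -1.03, camera adjusted p = 6e-04, adjusted p = 0.18 with an estimated correlation), with EXO1 at -3.37, the replication licensing gene CDC6 at -3.20 and CCNE1 at -2.69. G2/M genes were lower in 32 of 49 and higher in 15, which did not pass (camera adjusted p = 0.15); AURKB changed by -2.32 and CDC25C by -2.06. PRC1 (2.78) shares 64.4% of its sequence words with other genes and is uncertain. Notch targets fell in 11 of 13 and rose in 1 (median -1.18, camera adjusted p = 0.016, adjusted p = 0.18 with an estimated correlation), with DTX1 at -2.80 and NOTCH3 at -1.85. The T-leukaemia transcription factor circuit fell in 14 of 15 and rose in 1 (median -0.55, camera adjusted p = 0.016, adjusted p = 0.26 with an estimated correlation), with MYB at -1.96 and ERG at -1.89. Ribosomal protein genes rose in 68 of 69 with 0 lower (median 1.42, camera adjusted p = 8.8e-15, adjusted p = 0.31 with an estimated correlation), RPLP2 by 2.05, RPLP1 by 2.03 and RPL37A by 1.97, while the treated total was 58.3% of DMSO. Their median without scaling factors was 0.99.

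**Figure D3:**
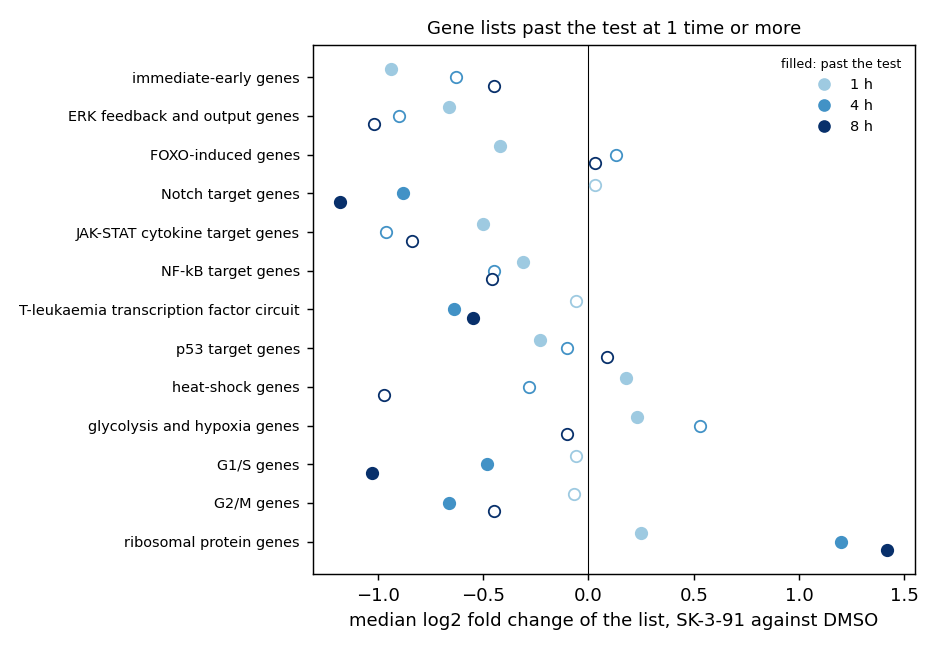
Median log2 fold change, SK-3-91 against DMSO, of the gene lists that passed camera with the preset correlation at 1 or more times; filled points passed and open points did not. Ribosomal protein genes lie at 0.25, 1.2 and 1.42 at 1, 4 and 8 h.

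The lists that passed at 1 h only held members of both directions later. A lost call did not always go with a smaller change. Median log2 fold changes at 1, 4 and 8 h were -0.66, -0.90 and -1.02 for ERK genes. They were -0.50, -0.96 and -0.84 for JAK-STAT targets and -0.31, -0.45 and -0.46 for NF-kB targets. With TMM factors smaller decreases followed for immediate-early genes (-0.94, -0.63 and -0.45). Without scaling factors their medians were -0.97, -0.92 and -0.88, so how far the decrease shrank depends on the scaling. With TMM factors medians of FOXO-induced genes (-0.42, 0.13 and 0.03) and p53 targets (-0.23, -0.10 and 0.09) turned. Without scaling factors they did not, at -0.44, -0.17 and -0.40 for FOXO-induced genes and -0.25, -0.39 and -0.34 for p53 targets. With upper-quartile factors the 8 h medians were -0.14 and -0.07, so the turn depends on the scaling. Immediate-early genes were lower in 9 of 14 (10 adjusted over the list alone) and higher in 3 at 4 h (camera adjusted p = 0.26), and lower in 8 and higher in 5 at 8 h (0.85); KLF6 rose by 1.95 and 3.35. ERK genes were lower in 7 of 12 at both times and higher in 3 and 4 (camera adjusted p = 0.43 and 0.46), with PHLDA1 at 2.64 and DUSP7 at -1.83 at 4 h. FOXO-induced genes were higher in 10 of 21 at both times and lower in 9 and 8 (camera adjusted p = 0.55 and 0.46); without scaling factors 6 and 7 were higher and 12 lower at both times. At 8 h SESN1 rose by 3.01 and CITED2 fell by 2.55. JAK-STAT targets were lower in 8 of 10 and higher in 1 at both times (camera adjusted p = 0.17 and 0.22), with CISH at -3.10 at 4 h. NF-kB targets were lower in 8 and 10 of 14 and higher in 3 and 4 (camera adjusted p = 0.23 and 0.47), with NFKBIE at -3.12 at 4 h and CD83 at -2.86 at 8 h. p53 targets were higher in 10 and 12 of 24 and lower in 11 and 9 (camera adjusted p = 0.83 and 0.42); without scaling factors 5 and 8 were higher and 13 lower at both times. At 8 h ZMAT3 rose by 3.52, PPM1D by 2.13 and GADD45A by 1.71. Heat-shock genes were lower in 12 of 18 at both times and higher in 6 and 4 (camera adjusted p = 0.46 and 0.13), with SERPINH1 at -2.34 and -2.92. Glycolysis and hypoxia genes were higher in 16 and 12 of 30 and lower in 12 and 15 (camera adjusted p = 0.24 and 0.8); at 8 h the lactate exporter gene SLC16A3 changed by -4.22 and PFKFB4 by -3.55. At 1 h the lists that passed only later did not: Notch targets were higher in 3 and lower in 4 of 13 (camera adjusted p = 0.46), the T-leukaemia circuit higher in 3 and lower in 7 of 15 (0.2), G1/S genes higher in 10 (11 adjusted over the list alone) and lower in 20 of 45 (0.13), and G2/M genes higher in 8 and lower in 19 of 49 (0.63), or 15 and 15 with RLE factors.

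The remaining lists passed at no time. MYC-driven nucleolar genes were lower in 8, 25 and 27 of 39 at 1, 4 and 8 h (26 at 4 h adjusted over the list alone) and higher in 12, 12 and 9 (camera adjusted p = 0.46, 0.086 and 0.053); POLR1B changed by -1.95 at 4 h and GNL3 by -2.44 at 8 h. T-lineage genes were lower in 7 (8 adjusted over the list alone), 13 and 17 of 29 and higher in 11, 12 and 8 (0.43, 0.84 and 0.17); the adhesion receptor gene CD2 changed by -3.07 and -3.78 at 4 and 8 h and the recombinase gene RAG2, uncertain with 25.96% of its exon bases on the opposite strand, by -2.46 and -3.18. T-cell activation genes were lower in 4, 7 and 5 of 9 and higher in 1, 2 and 3 (0.23, 0.19 and 0.46), with CD69 at -2.24 at 4 h. ATF4 and stress response genes were lower in 10 (11 adjusted over the list alone), 13 and 16 of 27 and higher in 9, 9 and 10 (0.76, 0.76 and 0.34), with STC2 at -3.68 at 4 h and -4.61 at 8 h. Unfolded protein response genes were lower in 5 (6 adjusted over the list alone), 11 and 14 of 22 and higher in 8, 10 and 4 (0.46, 0.85 and 0.13); at 8 h XBP1 changed by -3.52 and MANF by -2.94. Sterol synthesis genes were lower in 7, 11 and 11 of 24 and higher in 11, 10 and 11 (0.8, 0.97 and 0.69); at 8 h MVK changed by -2.80 and MSMO1 by 2.31. Interferon-stimulated genes were lower in 8, 15 and 20 of 31 and higher in 10, 14 and 9 (0.46, 0.97 and 0.17), with IFIT5 at -1.58 at 1 h. DNA repair genes reported to need CDK12 were lower in 10 (9 adjusted over the list alone), 17 and 18 of 28 and higher in 4, 8 and 8 (0.57, 0.22 and 0.25), with TERF2 at -2.36 at 4 h. BCL-2 family genes were lower in 6, 7 and 7 of 13 and higher in 4, 5 and 4 (0.46, 0.57 and 0.71), with BMF at -3.20 at 8 h. Which side held more members was not the same with TMM, RLE, upper-quartile and no scaling factors for sterol genes at all 3 times, for ATF4, unfolded protein, MYC nucleolar, Notch and CRBN ligase genes at 1 h, and for T-lineage and interferon genes at 4 h. The same was found for FOXO-induced, protein kinase and CDK genes at 4 and 8 h, for p53 targets at 8 h and for G2/M genes at 1 h. In 8 of the 75 list tests the median, mean and test differed in sign, and 0 of these passed.

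Because SK-3-91 degrades kinases, transcripts of kinases and of the ligase were listed beforehand. Of 326 protein kinase genes, 62 rose and 107 fell at 1 h (61 and 106 adjusted over the list alone), 138 and 138 at 4 h, and 151 and 139 at 8 h (camera adjusted p = 0.43, 0.88 and 0.46). Without scaling factors 82 were higher and 201 lower at 4 h, and 96 and 191 at 8 h. At 8 h MAPK13 rose by 3.64 ± 0.20 and IKBKE changed by -2.82 ± 0.14. CDK and cyclin genes were higher in 5, 14 and 16 of 28 and lower in 12, 11 and 9 (camera adjusted p = 0.46, 0.46 and 0.24); without scaling factors 10 were higher and 15 lower at 4 h, and 11 and 15 at 8 h. CCNT2, a cyclin partner of CDK9, rose by 1.44 and 2.33 at 4 and 8 h. CRBN ligase components and neosubstrates were higher in 6, 5 and 8 of 21 (7 and 6 at 1 and 4 h adjusted over the list alone) and lower in 7, 14 and 11 (camera adjusted p = 0.93, 0.43 and 0.79), with DTWD1 at -2.53 at 8 h. Markers of other cells were mostly not among the genes measured. B-cell markers had 2 of 12 measured: CD79A rose by 0.34, 1.08 and 1.69 at 1, 4 and 8 h, the first not called without replicate 3 of DMSO at 1 h (0.28), and IGLL1 fell by 1.06 at 8 h. Of 16 myeloid markers 1 was measured, CD68, which rose by 1.26 at 4 h and 1.61 at 8 h. PECAM1, 1 of 13 fibroblast and endothelial markers, fell by 1.29 at 8 h. H2BC12, 1 of 58 histone genes, rose by 0.97 at 4 h and 0.82 at 8 h but shares 85.7% of its sequence words. Of erythroid, epithelial and mitochondrial genes 0 were measured.

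Of the fixed genes 16 were measured. MYC fell from 719 to 363 CPM at 1 h (log2 fold change -0.99 ± 0.04), from 747 to 386 at 4 h (-0.95 ± 0.04) and from 645 to 128 at 8 h (-2.33 ± 0.05; SE, n = 4 per group, edgeR adjusted p = 4e-35). MCL1, an anti-apoptotic BCL-2 family gene, fell by 0.99 at 1 h and 0.28 at 4 h and rose by 1.09 at 8 h. The immediate-early gene EGR1 changed by -1.10, -1.44 and -2.31, the ERK phosphatase gene DUSP6 by -0.63, -1.56 and -2.10 and the Notch target HES1 by -1.74, -0.34 and -0.64. DUSP6 and CDK4 share 40.5% and 43.2% of exon bases with exons on the opposite strand and are uncertain. Among kinases, AURKA fell by 0.34, 1.75 and 0.71, CDK12 by 0.13, 0.64 and 0.78, and LCK changed by 0.17, 0.15 and -1.24, the 4 h value being -0.15 without scaling factors. WEE1 changed by -0.96, -0.66 and 0.07 (edgeR adjusted p = 0.19 at 8 h, where it was -0.37 without scaling factors and -0.10 with upper-quartile factors). CDK6 changed by -0.05 (adjusted p = 0.33 in edgeR), 0.34 and 0.89, and CDK4 by 0.17, 0.29 and -0.95, with -0.01 at 4 h without scaling factors. The median of all genes moved by -0.299 at 4 h without scaling factors, close in size to the CDK6 rise, which may thus depend on the scaling. CDK9 changed by -0.20, -0.21 and 0.31, and CDK13 by -0.15, -0.33 and 0.17; at 8 h both were negative without scaling factors (-0.12 and -0.26). CDK7 changed by -0.23, -1.10 and -0.20, the 8 h value not called (edgeR adjusted p = 0.072) but called at -0.63 without scaling factors and at -0.37 with upper-quartile factors. CRBN, the substrate receptor of a ubiquitin ligase, changed by -0.14 (edgeR adjusted p = 0.028), -0.28 and 0.02 (0.81), the 8 h value being -0.41 without scaling factors and -0.15 with upper-quartile factors; the 1 h calls of CRBN and CDK7 were lost with RLE factors and DESeq2.

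**Figure D4:**
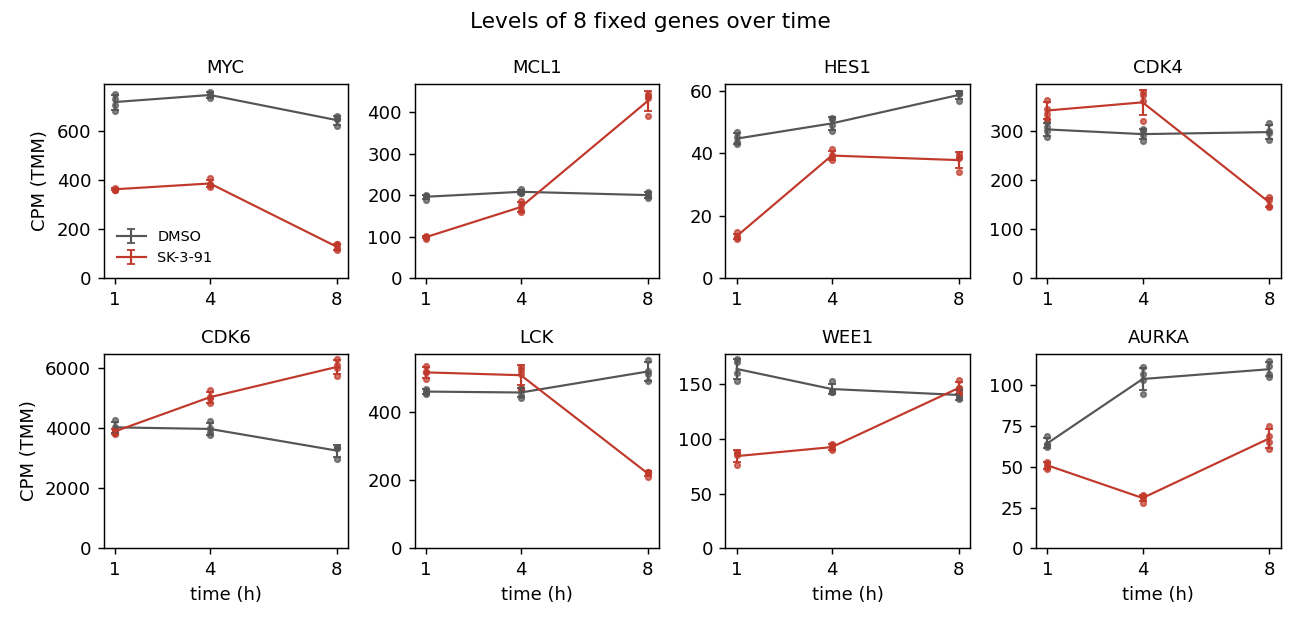
CPM of 8 of the fixed genes (MYC, MCL1, HES1, CDK4, CDK6, LCK, WEE1 and AURKA) against time in h; points are libraries, lines join group means and error bars are the SD (n = 4). MYC lies at a mean of 645 CPM in DMSO and 128 CPM in SK-3-91 at 8 h.

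Whether the response differed between times was tested as an interaction in edgeR. Between 1 and 4 h, 7901 of 9822 genes responded differently, 3986 upward and 3915 downward; between 4 and 8 h it was 6738, 3493 upward and 3245 downward. HES1 moved up by 1.40 ± 0.08 between 1 and 4 h (edgeR adjusted p = 1e-18) and AURKA by -1.41 ± 0.08, while MYC did not differ by the test (0.03 ± 0.06, adjusted p = 0.58). Between 4 and 8 h MCL1 moved up by 1.37 ± 0.06, MYC by -1.38 ± 0.06 and LCK by -1.39 ± 0.06. Without scaling factors the splits were 2672 upward and 5198 downward, and 2699 and 4113. The median difference of all genes then moved by -0.275 and -0.132. Small differences, and the absence of one for MYC between 1 and 4 h, may thus depend on the scaling. Against a minimum fold of 1.5 the counts were 3457 and 1805.

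Calls at different times overlapped, with separate DMSO libraries at each time. At 4 and 8 h, 3265 genes were higher at both and 3756 lower at both, against 1703.4 and 2169.2 for independent lists; 454 and 364 were called in opposite directions. At 1 and 4 h the counts were 1905 and 2030 (1027.1 and 1326.8 for independent lists), and at 1 and 8 h 1473 and 1645 (1011.9 and 1389.2). Opposite calls numbered 360 (higher, then lower) and 586 (lower, then higher) at 1 and 4 h, and 776 and 975 at 1 and 8 h, against 1177.1 and 1194.2 for independent lists at the latter 2 times. Among genes changed at least 2-fold at both 4 and 8 h, 827 were higher, 1484 lower and 0 opposite.

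DMSO-treated cells also changed over time. From 1 to 4 h ADM rose by 4.06 ± 0.22 on the log2 scale (edgeR adjusted p = 1e-17, n = 4 per group), the stress-induced gene DDIT4 by 2.33 ± 0.07 (uncertain, with 41.2% of its exon bases on the opposite strand) and BHLHE40 by 1.61 ± 0.09, while the zinc exporter gene SLC30A1 fell by 1.88 ± 0.09. G2/M genes rose in 43 of 49 with 0 lower and G1/S genes fell in 33 of 45 with 3 higher. From 4 to 8 h PFKFB4 rose by 2.64 ± 0.08, MIR210HG by 2.25 ± 0.10 and SLC16A3 by 2.11 ± 0.11, and glycolysis and hypoxia genes rose in 28 of 30 with 0 lower. These genes beyond the fixed ones were chosen after their values were seen. ADM thus averaged 0.6, 10.2 and 37.8 CPM in DMSO at 1, 4 and 8 h against 0.394, 0.569 and 0.89 CPM with SK-3-91, so its decrease at 4 and 8 h was measured against a rising DMSO level. The same holds between 4 and 8 h for SLC16A3 (5.57 to 24 CPM in DMSO, 1.66 to 1.31 CPM with SK-3-91), PFKFB4 (9.9 to 61.7 and 9.03 to 5.28 CPM) and EGR1 (13.6 to 26.2 and 4.98 to 5.33 CPM). RAB20 and STC2 also rose in DMSO from 4 to 8 h, by 1.24 and 1.28, and DTX1 rose by 1.21 from 1 to 4 h. The decreases of RAB20 and STC2 at 8 h and of DTX1 at 4 h thus carry the same limit. It holds for lists too. The median log2 change in DMSO was 0.67 for glycolysis and hypoxia genes from 4 to 8 h, where their median response went from 0.53 to -0.10. For G2/M genes it was 0.29 from 1 to 4 h, with AURKA at 64.5 and 104 CPM in DMSO and at 50.9 and 30.8 CPM with SK-3-91. Part of the G2/M decrease at 4 h was thus measured against a rising DMSO level. Heat-shock genes rose in DMSO from 1 to 4 h in 14 of 18 with 0 lower (median 0.28). Their median response went from 0.18 to -0.28. Unfolded protein response genes rose in DMSO from 4 to 8 h in 15 of 22 with 1 lower (median 0.20). Their median response went from -0.19 to -0.41. edgeR called 3450 genes between 1 and 4 h (1573 higher, 1877 lower) and 3019 between 4 and 8 h (1563 higher, 1456 lower; 1266 and 1829 without scaling factors). Against a minimum fold of 1.5 these were 40 and 50. Some DMSO levels fell between 1 and 4 h, in examples also chosen after their values were seen. ID3 averaged 41.3 and 19.7 CPM in DMSO (6.12 and 2.77 CPM with SK-3-91). PIM1 averaged 43.3 and 20 CPM in DMSO (11.2 and 8.14 CPM with SK-3-91). Their decreases at 1 h were thus measured against a higher DMSO level than at 4 h. FOXO-induced genes fell in 10 of 21 and rose in 1 in DMSO in that interval.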

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

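No test in this part was chosen after its result was seen. Responses that differed between times were found by interaction tests in edgeR. They covered 7901 genes between 1 and 4 h and 6738 between 4 and 8 h, and 25 of 32 tests of the fixed genes. Between 1 and 4 h the log2 response of HES1 moved by 1.40, MCL1 by 0.71, CDK6 by 0.39, WEE1 by 0.31, CDK13 by -0.18, CDK12 by -0.51, CDK7 by -0.87, DUSP6 by -0.92 and AURKA by -1.41. Between 4 and 8 h MCL1 moved by 1.37, AURKA by 1.04, CDK7 by 0.90, WEE1 by 0.72, CDK6 by 0.55, CDK9 by 0.53, CDK13 by 0.50 and CRBN by 0.29. In the same interval HES1 moved by -0.30, DUSP6 by -0.55, EGR1 by -0.86 (13.6 to 26.2 CPM in DMSO, 4.98 to 5.33 CPM with SK-3-91), CDK4 by -1.24, MYC by -1.38 and LCK by -1.39. Without scaling factors the median difference of all genes moved by -0.275 between 1 and 4 h and by -0.132 between 4 and 8 h. Differences near those sizes, such as those of WEE1 and CDK6 between 1 and 4 h, may thus depend on the scaling.

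Other splits of the same libraries were fitted to ask whether chance can be excluded. In each treatment comparison 1 of 35 splits, the real one, called as many genes in either direction, the smallest share that these splits allow. At 1 h the other splits called at most 0 genes against 2448 and 2889. At 4 and 8 h they called at most 0 against 4121 and 4511, and 4060 and 4723. Each of them mixes treated and DMSO libraries, which puts the treatment effect into the spread. Their low counts therefore do not show how many calls chance gives, and the splits alone do not exclude chance. For the changes in DMSO 1 of 35 splits each reached the real count, with 3450 against at most 5 and 3019 against at most 260. The same limit holds there, since the other splits mix libraries of different times. For the responses, 1 of 100 splits reached 7901 (highest other 7511) and 2 of 100 reached 6738 (highest other 7646). These splits do not test whether the response differed: mixing treated and DMSO libraries at a time puts the treatment effect into the spread. The high values come from the 5 and 3 drawn splits that keep the real treatment grouping at 1 of the times, and the rest called at most 0 genes. For the differing responses chance is therefore addressed by the interaction tests alone.

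Single libraries stood apart from the other 3 of their group in 18 of 348 groups tested, where chance gives about 17.4. In mean log2 CPM of lists at 1 h, replicate 1 of DMSO was at 4.971 for immediate-early genes (others 4.947 to 4.949) and 4.313 for ERK genes (4.243 to 4.252), replicate 2 of DMSO at 6.158 for ATF4 genes (6.117 in the others) and replicate 1 of SK-3-91 at 7.259 for MYC nucleolar genes (7.267 to 7.268). At 4 h replicate 4 of DMSO was at 4.932 for interferon genes, replicate 1 of SK-3-91 at 6.471 for unfolded protein genes and replicate 2 of SK-3-91 at 6.694 for G1/S genes; at 8 h replicate 3 of DMSO was at 5.531 for BCL-2 genes. In CPM at 4 h, replicate 4 of DMSO was at 0.701 for PKD1L3 (others 0.313 to 0.375), replicate 1 of DMSO at 13.3 for EOMES and 153 for WEE1, and replicate 1 of SK-3-91 at 5.75 for EGR1. At 8 h replicate 3 of SK-3-91 was at 13.5 for PKD1L3 and 3.87 for ZNF672 (2.61 to 2.67), and replicate 1 of SK-3-91 at 5.34 for DUSP6 (2.95 to 3.33). In DMSO at 8 h TNFSF13B was at 0.204 in replicate 3, HES1 at 56.7 in replicate 1 and CDK6 at 2950 in replicate 4 (3320 to 3360).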

How the results depend on the processing

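limma-trend on the deposited log2 values was chosen after the data were seen; the other alternatives were planned. Of 370 named gene values, the alternatives other than the minimum fold left the call unchanged in 12541 cases. With the direction kept, they lost the call in 18 and gained it in 7. In 14 cases the direction turned and the main or the alternative fit called the gene. Among these, CRBN and WEE1 at 8 h were not called in the main fit. Of the unchanged cases 8867 came from leaving out single libraries, and 370 from each of the 2 filters that removed no gene. Without scaling factors CDK4 at 4 h was -0.01, LCK at 4 h -0.15, and at 8 h CRBN -0.41, CDK9 -0.12, CDK13 -0.26 and WEE1 -0.37. limma-trend on the deposited log2 values gave -0.01, -0.15, -0.29, -0.10, -0.25 and -0.34 for the same genes, and upper-quartile factors gave -0.15 for CRBN and -0.10 for WEE1 at 8 h. The reversals without scaling factors follow the scaling, since the median of all genes moved by -0.299 at 4 h and -0.431 at 8 h. With limma-trend, which also changed the test, that median moved by -0.173 and -0.215. A minimum fold of 1.5 lowered the calls to 5 higher and 573 lower at 1 h, 1938 and 2525 at 4 h, 2496 and 3052 at 8 h, 3457 and 1805 for the differing responses, and 40 and 50 in DMSO, since it asks for a larger change. With a log2 change of at least 1, genes called alike numbered 215 at 1 and 4 h, 2311 at 4 and 8 h, and 173 at 1 and 8 h. No count moved by over 1.5 times when a library was left out; the widest range was 2306 to 3267 for DMSO between 4 and 8 h. Leaving out single libraries ended the 1 h calls of CDK7 (replicates 1, 3 and 4 of DMSO and 1, 2 and 4 of SK-3-91; -0.32 to -0.19 over all), of CRBN (replicates 2 and 3 of DMSO and 2 and 4 of SK-3-91; -0.17 to -0.11) and of CD79A (replicate 3 of DMSO; 0.28), called CDK7 at 8 h without replicate 2 of DMSO (-0.25) or of SK-3-91 (-0.29), and brought MYC nucleolar genes at 8 h to a lowest camera adjusted p of 0.048. An estimated correlation ended 15 of the 18 list calls. The absence of a filter and the filter at a CPM of 1 removed no gene and so tested nothing. The planned fits on log2(RPKM + 0.1) and log2(RPKM + 1) were not run, because the table was already on a log2 scale. Replicate numbers did not pair the libraries: same-number correlations of 12 pairs ran from -0.119 to 0.022, and 0 treated libraries correlated best with their own number. With the replicate block 2448 genes were higher and 2891 lower at 1 h, 4123 and 4504 at 4 h, and 4059 and 4714 at 8 h.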

Other observations

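The tests of unscaled ribosomal protein counts and of sequencing depth, and the interval for the span difference, were chosen only after the result was seen. Genes with ZNF symbols, which encode zinc-finger proteins, were noticed as a group among the largest decreases at 1 h. Of 352 measured, 287 fell and 9 rose at 1 h in edgeR (median log2 fold change -0.65), 268 fell and 50 rose at 4 h (-1.04), and 246 fell and 80 rose at 8 h (-0.87). At least 2-fold decreases numbered 90, 184 and 162.

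The fall of ZNF genes at 1 h was weighed against technical causes. The 118 ZNF genes sharing the fewest sequence words with other genes had a median of -0.48, below random lists of other genes (-0.04 to 0.07), which argues against reads shared between paralogs as the whole cause. Lists matched on GC content, transcript length and expression lay between -0.11 and -0.03 against -0.65, which argues against those properties. A candidate explanation is a faster loss of short-lived transcripts when transcription falls, a hypothesis for which no half-lives were tested.

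The rise of ribosomal protein genes at 8 h, a median of 1.42, lay above lists matched on GC content, transcript length and expression (0.30 to 0.86), which argues against those properties as the whole cause. Level ribosomal protein reads beside falling reads of other genes stay open: their unscaled counts had a median log2 ratio of 0.21, against -1.32 for all genes, and their share of counts went from 2.29% in DMSO to 4.65%. Since the totals differ and no spike-in was analysed here, a gain and a slower loss cannot be told apart.

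The lower treated total at 8 h may come from less RNA per cell, fewer reads sequenced or reads outside the genes measured. Without the 100 most abundant genes the treated total was 54.7% of DMSO, so the lower total was not confined to those genes. Whether abundant RNA outside the genes measured took reads cannot be told from this value. A difference in sequencing depth cannot be told apart: the unscaled log2 ratios spanned 3.18 from the 10th to the 90th percentile, more than 1 shared factor gives, but the number of reads sequenced is not used here.

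Long genes might need transcription kinases more than short genes; no kinase protein was measured. At 1 h the median log2 fold change of the longest quintile by genomic span minus that of the shortest quintile was -0.09 (bootstrap interval over genes -0.11 to -0.07). The bound set beforehand for excluding the idea, -0.1, lies inside that interval, so it was not decided. The idea needed -0.2 or lower, which lies outside the interval, and a median of the longest genes below that of lists matched on expression and transcript length. At 1 h that median lay above them, at -0.03 (bootstrap interval -0.04 to -0.01) against -0.07 to -0.04, though these ranges meet. It was 0 against -0.26 to -0.16 at 4 h and 0.04 against -0.25 to -0.13 at 8 h. The requirement set beforehand did not cover those later times. From the shortest to the longest quintile the medians at 1 h were 0.06, 0.02, 0.01, 0 and -0.03, the direction that the idea predicts. The 1 h values thus fell short of the requirement set for the idea but did not exclude it. Transcription itself was not measured. At 8 h the shortest quintile was at -0.15.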
